A study of Mus musculus with 4 samples.

How the data were processed

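RNA of IRF8-GFP negative and IRF8-GFP positive LMPP from mouse bone marrow, 2 samples each, was hybridized to 4 one-colour Agilent 8x60K mouse gene expression arrays. Per the labels' protocols, cells were enriched on magnetic columns and sorted by flow cytometry, total RNA was extracted with a spin-column kit for small samples, and it was labelled with Cy3 by a low-input amplification kit. Per the file headers, the scans were read with Agilent Feature Extraction 10.7.3.1, and each spot has a processed intensity that is background-subtracted and detrended but not normalized between arrays, a raw median intensity, a background intensity, and flags for signal well above background, saturation and outliers. The deposited matrix of the series holds intensity values that the authors had quantile normalized, judging from the values: all 4 columns contain the same sorted values (median 31.9), and their order matches the processed signals (Spearman correlation 1 on every array). Its scale is linear, and how it was centred is not given in the sources used here. All 4 arrays lie on 1 slide and were scanned on 1 day, so no batch of slide or scan day could be set apart. On every array 9 of 10 scanner quality metrics were in range, the exception being the net signal of negative controls.

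Control spots and spots marked as outliers (0.174% to 0.233% per array) were left out, and 12 of 55681 probes, whose spots were all outliers on an array, were dropped. No spot was saturated. Processed signals of a probe's spots were averaged, taken to log2, and the array's 75th percentile of the 55669 probes was subtracted. That percentile was a signal of 438 and 543 on the negative and 318 and 414 on the positive arrays. A probe was kept when it was well above background (at least 0.5 of its spots) on both arrays of 1 or both groups, which left 30478 probes. The dim end of the scale is therefore limited by background, and the number of arrays limits precision.

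The files hold accessions and no gene names. They were matched without version to RefSeq transcripts of the GRCm38.p6 annotation, used only for names and for the order of genes because the arrays were designed on another build. This named 26756 probes with 1 symbol (20280 symbols), and 28913 probes had none and stayed unnamed. A gene was represented by its brightest kept probe, giving 22362 genes and unnamed transcripts, of which 13341 had a symbol. Among these, 8417 passed the threshold (5882 higher and 2535 lower).

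The comparison was fitted on all 4 arrays with limma 3.58.1 (lmFit and eBayes, no trend, no block) in R 4.3.3, as positive minus negative, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The prior SD was 0.0749 on the log2 scale with 2.05 prior degrees of freedom beside 2 residual ones. An exact permutation test of 2 against 2 arrays cannot go below p = 0.333, so the p-values rest on the model. Where a probe was not well above background on any array of the dimmer group, the change is given as "at least N-fold", the bright group's mean against the mean, per array, of the higher of the dim value and the lowest signal among probes well above background. Gene lists were compared with all other genes by camera with a preset correlation of 0.01, adjusted over 20 lists. Beyond these, 2 sets, the genes of the sorting gate and sex-linked genes, were described and not tested. Lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The named genes are Irf8 and the sorting gate genes, the 10 largest fitted increases and 10 largest decreases past the threshold with groups that do not overlap and a proper gene symbol, and up to 4 members of each list past the threshold with the largest absolute change. Not every gene that this rule takes is printed. Further members are given as examples of what their list holds and were chosen after their values were seen.

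The alternatives were the replicate number as a block, each array left out in turn (the lone array then being assumed to vary like the other group), normexp background correction (offset 50), quantile normalization, centring on probes above background on all arrays, the authors' matrix values, no filter or a stricter one on dim probes, an intensity trend with and without robust estimation, the mean of a gene's probes, probes in place of genes, adjusted p of 0.01 and 0.1, an estimated correlation in camera, and fry. The files have no mean spot signal, so normexp used the median spot and background signals. Spike-in scaling (mean of 7 bright E1A control probes), cyclic loess, which removes any trend of the difference with brightness, and centring on the median of the tested genes were added after seeing the data.

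The fit and the list tests were tested on simulated data with the real probe means and spreads drawn from the fitted prior, for the comparison of 2 against 2 arrays over 22362 genes with 200 genes changed. Of 50 changed genes at each size, 0 were recovered at a log2 size of 0.25 and 0 at 0.5, 24 (48%) at 1 and 46 (92%) at 2, and 5 of 22137 unchanged genes were called. With so few changed genes the adjustment was stricter than in the data, where 13390 genes passed. These shares therefore do not give the power of the reported fit. A list of 25 genes shifted by 0.5 was recovered by camera with the preset correlation (adjusted p = 4.58e-34), and 0 of the 19 other lists were called. This was a single draw with noise independent between probes, so it does not test the preset correlation on lists whose genes vary together. Figures were drawn with matplotlib 3.10.9.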

Results

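Gene expression was measured in lymphoid-primed multipotent progenitors (LMPP), an early blood-forming cell of the mouse bone marrow that can still give rise to lymphoid and myeloid cells. The cells came from mice in which green fluorescent protein (GFP) had been knocked in to report IRF8, a transcription factor needed for the development of dendritic cells and monocytes. They were sorted as lineage-negative, IL-7R-negative, Sca-1-positive, CD117-positive, CD150-negative, CD34-positive and CD135-positive cells, and split by the reporter into an IRF8-GFP negative group and an IRF8-GFP positive group. Each group had 2 arrays, labelled exp 1 and exp 2 in both groups, and the comparison asks which transcripts differ between LMPP with and without IRF8 reporter signal. The labels do not say that the 2 arrays of a group came from separate animals, or that arrays of the same number belong together, so the p-values measure only the spread between these arrays, which may be technical. On the negative arrays 33506 and 33681 of 59305 spots were well above background, and on the positive arrays 29631 and 30266. The number of arrays limits the precision of every value below.

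Irf8 itself followed the sort. Its log2 signal, relative to each array's 75th percentile, was 1.62 ± 0.03 (SD, n = 2) in IRF8-GFP negative LMPP and 5.17 ± 0.06 (SD, n = 2) in positive LMPP, a log2 difference of 3.55 (SE 0.06) or 11.7-fold, with a limma adjusted p of 0.000802. Irf8 was well above background on all 4 arrays, so the negative group held measurable Irf8 transcript.

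The genes of the sorting gate did not all stay level. Il7r, which encodes the interleukin-7 receptor chain that the sort excluded at the surface, was 5.26-fold higher in the positive group (log2 difference 2.40, SE 0.06, limma adjusted p = 0.000835). Ly6a, which encodes Sca-1, was 1.94-fold lower (log2 difference -0.96, SE 0.07, adjusted p = 0.00222), and Kit, which encodes CD117, was 1.31-fold lower (log2 difference -0.39, SE 0.06, adjusted p = 0.00769). Kit did not pass without either negative array (adjusted p of up to 0.0597). Cd34 and Flt3 (CD135) had log2 differences of 0.26 (SE 0.06, adjusted p = 0.0249) and 0.25 (SE 0.06, adjusted p = 0.0257), which lie only 0.10 and 0.09 above the median of all genes, 0.16. Both signs turned under quantile normalization, in the authors' deposited matrix values, with spike-in scaling and with the brightness trend removed, and neither gene passed without negative replicate 1, negative replicate 2 or positive replicate 2 (adjusted p of up to 0.134 for Cd34 and 0.133 for Flt3, which did not pass without positive replicate 1 either), so no direction can be given for them. Slamf1, which encodes CD150, was above background on 0 of 4 arrays and was not tested.

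The groups differed widely. Of 22362 genes and unnamed transcripts tested, 13390 passed an adjusted p of 0.05 in limma, 8611 higher and 4779 lower in the positive group. With a change of at least 2-fold there were 1774, of which 520 were higher and 1254 lower. In 461 of these (47 higher and 414 lower) the dimmer group was not well above background on any array, so that only a lower bound of the change is known. The median log2 difference over all genes was 0.16, and small differences are best read against it. That median was 0.04 with quantile normalization and in the deposited matrix values, 0.02 with the brightness trend removed and -0.15 with spike-in scaling. The 64.3% share of higher calls was set by the scaling: it was 52.6% with quantile normalization, 52.4% in the deposited matrix values, 49.1% with the brightness trend removed and 27.9% with spike-in scaling, the last 2 chosen after seeing the data. It also rose with brightness, from 995 higher and 1455 lower calls in the dimmest of 4 equal groups of genes to 3750 higher and 439 lower in the brightest. Without negative replicate 1 the calls fell to 7612 (4760 higher and 2852 lower) and without negative replicate 2 to 7723 (4808 higher and 2915 lower). The count at 2-fold was 651, with 272 higher and 379 lower, under normexp background correction, which compresses dim signals.

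Replicates lay closer together than groups. Across the tested genes, which are not independent replicates, the Pearson correlation of log2 signals was 0.998 between the negative arrays, 0.997 between the positive arrays and 0.980 to 0.981 between arrays of different groups. Both arrays of one group lay beyond both arrays of the other in 18377 genes (82.2%), where chance gives 33.3% for a single gene. All genes share the same 4 arrays. A shift common to many genes, such as the median of 0.16 or the trend with brightness, also separates the groups. The share therefore does not count the genes that differ between the cells.

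**Figure D1:**
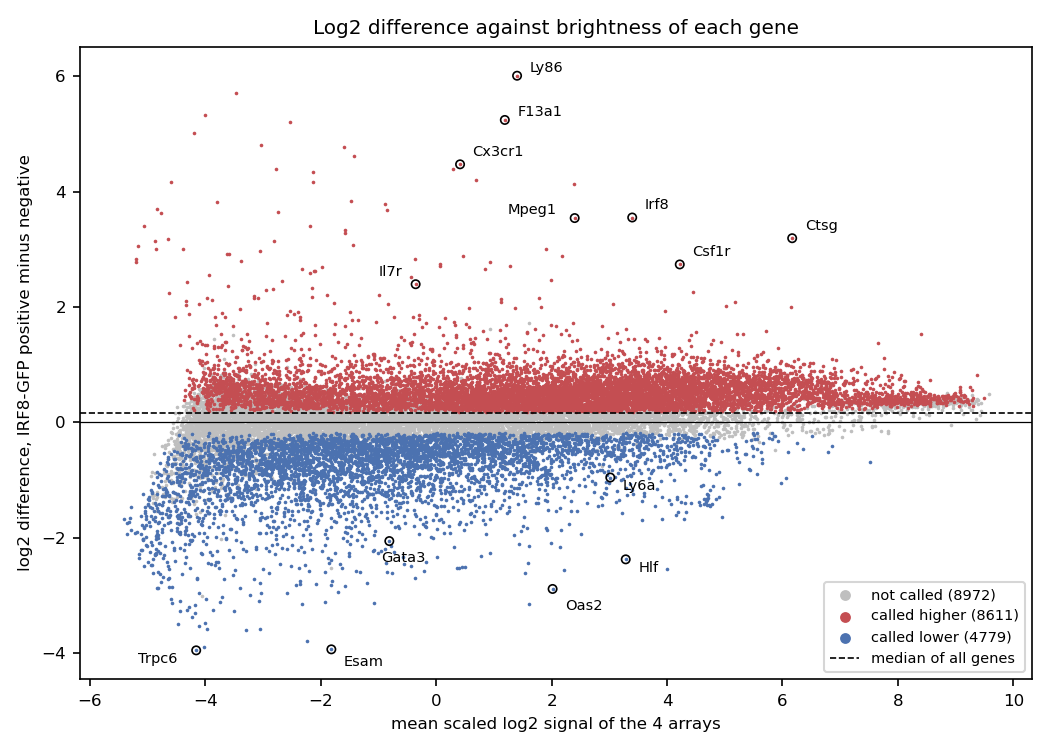
Log2 difference (IRF8-GFP positive minus negative, 2 arrays each) of the 22362 genes and transcripts against their mean scaled log2 signal over 4 arrays. Genes past an adjusted p of 0.05 are coloured (8611 higher, 4779 lower), the dashed line is the median of all genes at 0.16, and the higher calls lie mostly among the brighter genes.

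The largest increases measured on both sides were those of Ly86 (64.6-fold), an extracellular partner of the Toll-like receptor homologue Cd180, F13a1 (37.9-fold), the A chain of coagulation factor XIII, Mefv (24.7-fold), which encodes pyrin, Cx3cr1 (22.3-fold), the fractalkine receptor, and Hp (18.4-fold), which encodes haptoglobin. Their log2 differences ran from 4.20 (SE 0.08) for Hp to 6.01 (SE 0.05) for Ly86, and both positive arrays lay above both negative arrays for each. The limma adjusted p-values were 0.000691 for Ly86, 0.000802 for F13a1, Cx3cr1 and Hp, and 0.000852 for Mefv. The 2 probes of Mefv differed in size, with log2 differences of 1.91 and 4.63. Rab7b, a small GTPase of the late endosome, was 20.2-fold higher (log2 difference 4.34, SE 0.07, adjusted p = 0.000802) and Epha2, an ephrin receptor, 18.1-fold higher (log2 difference 4.18, SE 0.20, adjusted p = 0.00145), each with only 1 of the 2 negative arrays above background. Apba1 was at least 17.0-fold higher (adjusted p = 0.0013), Tctex1d1 at least 10.2-fold (adjusted p = 0.000852) and Clec9a, a lectin receptor of conventional dendritic cells and their precursors, at least 8.04-fold (adjusted p = 0.000852), since none of them was well above background in the negative group.

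Among the 10 decreases with the largest fitted differences, Esam alone was measured in both groups. This adhesion molecule of endothelium and blood stem cells was 15.3-fold lower in the positive group (log2 difference -3.94, SE 0.08, limma adjusted p = 0.000802). The other 9 were not well above background in the positive group and have only bounds: Mamdc2 was at least 6.72-fold lower, Fam181b at least 5.68-fold, Lrrn3 at least 3.78-fold and the cation channel gene Trpc6 at least 3.52-fold. For Ubl4b the bound was 3.51-fold, for Nap1l3 3.34-fold, for Gdf15, a cytokine of the TGF-beta family, 2.77-fold, for Postn, which encodes the matrix protein periostin, 2.73-fold, and for Rassf6 2.41-fold. Their adjusted p-values lay between 0.000802 (Lrrn3, Postn, Rassf6 and Trpc6) and 0.0023 (Ubl4b).

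**Figure D2:**
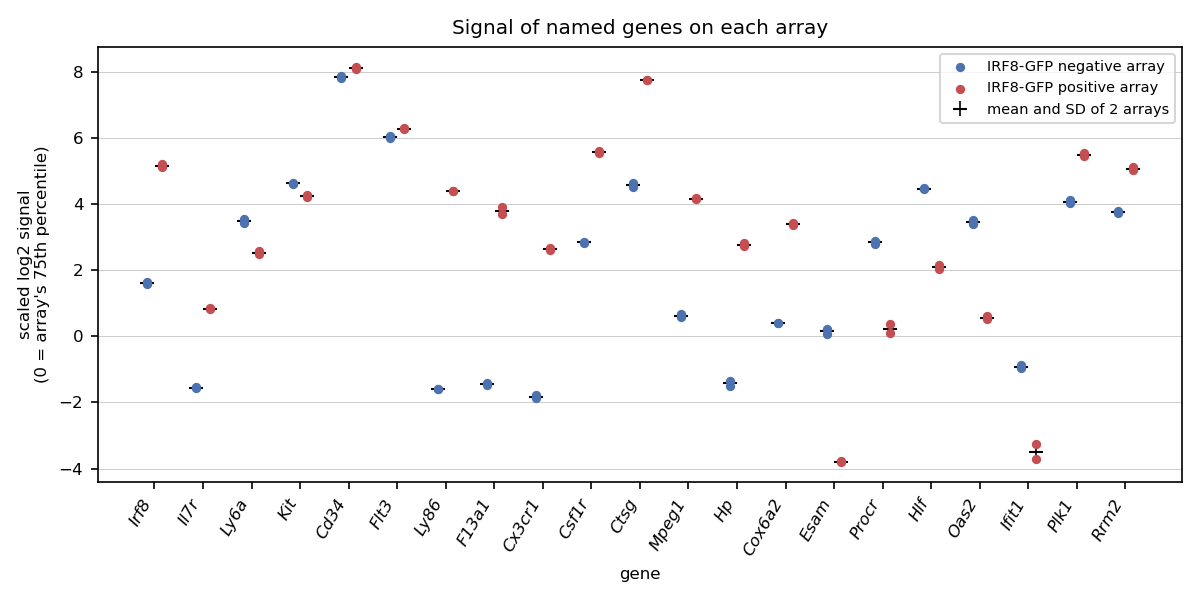
Scaled log2 signal (0 is the array's 75th percentile) of 21 named genes on each array, with IRF8-GFP negative arrays in blue and positive arrays in red, and the mean and SD of the 2 arrays of a group in black. The groups stand apart for every gene drawn, from Ly86, 64.6-fold higher, to Esam, 15.3-fold lower, while Cd34 and Flt3 differ by about the median of all genes, with signs that turn under other scalings.

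Counts of list members that rose or fell are best read against the 13341 tested genes with a symbol, of which 5882 were higher and 2535 lower. Of 20 gene lists fixed beforehand, 12 shifted relative to all other genes in camera with a preset correlation of 0.01, 5 upward and 7 downward. The calls for S phase, G2 and M phase, stem cell, megakaryocyte and erythroid, and interferon-stimulated genes were kept under all 17 alternatives with that correlation. The other 7 lists lost their call under 1 or more of them. With an estimated correlation camera called none of the 20 lists, with 2 below an unadjusted p of 0.05, and the adjusted p was 0.292 for 11 of the 12 and 0.346 for the lysosome list. The fry test, which does not compare a list with other genes, called 18 lists as moving one way. In 1 set of simulated arrays, with noise independent between probes, camera with an estimated correlation also missed a list shifted by 0.5 (adjusted p = 0.104). A single list in a single draw does not measure its power, so the lack of calls cannot be set aside. The estimated correlations of the 12 lists ran from -0.12 for stroma and endothelium to 0.325 for G2 and M phase, against the preset 0.01. For the stem cell list the estimate of -0.0044 lay below the preset, yet its unadjusted camera p went from 6.67e-13 to 0.0147. Estimates for the B lineage (-0.063), T, NK and innate lymphoid (-0.042), immediate early (-0.045) and stroma lists were also below the preset. A higher correlation therefore does not account for the loss of these calls.

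Monocyte genes rose in part. Of 21 tested monocyte and macrophage genes 11 rose, 4 fell and 6 passed in neither direction (11 and 5 when adjusted over the list alone). F13a1 and Cx3cr1 led it, followed by the chemokine receptor gene Ccr2 at 14.3-fold (log2 difference 3.84, SE 0.13) and Mpeg1, which encodes perforin-2, at 11.7-fold (3.54, SE 0.06). Lyz2 (0.01) and Lyz1 (0.05), which encode lysozyme, and Klf4 (-0.04) stayed close to 0, and Tlr4 (-0.99) and Itgam (-0.52), the CD11b gene, fell. The list as a whole did not shift against other genes in camera (adjusted p = 0.147), although it passed with spike-in scaling (0.026) and with the mean of each gene's probes (0.0354), in a range of 0.026 to 0.46 over the 17 alternatives. Its median of 0.36 turned to -0.05 with the brightness trend removed.

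Granule genes mostly rose. Of 15 tested neutrophil and granule genes 9 rose, 2 fell and 4 did not pass, with the same counts when adjusted over the list alone. Hp, the cathepsin G gene Ctsg at 9.15-fold (log2 difference 3.19, SE 0.07), Ms4a3 at 7.38-fold (2.88, SE 0.06) and the neutrophil elastase gene Elane at 2.97-fold (1.57, SE 0.06) rose most, with limma adjusted p-values from 0.000802 to 0.0013. Mpo (1.53) and Prtn3 (1.46) rose as well. S100a9, a calcium-binding protein abundant in mature neutrophils, fell (-1.11, adjusted p = 0.00186), Camp lay at -0.09 and S100a8 at -1.16 without passing, Lcn2 rose (0.43, adjusted p = 0.0158), and Ltf, Ngp and Mmp8 were not above background on any array. The list did not pass camera (adjusted p = 0.147), but passed with spike-in scaling (0.00579), quantile normalization (0.04996), the deposited matrix values (0.0488) and the brightness trend removed (0.0399), in a range of 0.00579 to 0.284 over the 17 alternatives.

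Conventional dendritic cell genes shifted upward (camera adjusted p = 0.0226, and 0.292 with an estimated correlation). Of 28 on the array 21 passed the filter on dim probes, and Xcr1, Cadm1 and Irf4 were among those not tested. Of the 21 tested, 12 rose, 1 fell and 8 did not pass (the same when adjusted over the list alone), with a median log2 difference of 0.27 against 0.16 for all genes. The 12 include Flt3, for which no direction can be given. Besides Clec9a and Rab7b, the CD11c gene Itgax rose 2.54-fold (1.34, SE 0.06) and Batf3, a transcription factor of one branch of these cells, 2.26-fold (1.18, SE 0.05), while Zbtb46 (0.20) and Wdfy4 (0.14) did not pass and Relb (-1.05) fell. The call ended under 7 of the 17 alternatives, with an adjusted p of up to 0.14, and with spike-in scaling the median turned to -0.04, with 5 higher and 2 lower. With quantile normalization and in the deposited matrix values 7 were higher and 4 lower, and with the brightness trend removed 7 and 3.

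Plasmacytoid dendritic cell genes moved both ways. Of 16 tested 5 rose, 6 fell and 5 did not pass (the same when adjusted over the list alone). Ly6d, a surface protein of lymphoid progenitors, was 10.1-fold higher (log2 difference 3.34, SE 0.15, limma adjusted p = 0.00141) and Cox6a2 8-fold higher (SE 0.06, adjusted p = 0.000802). Ccr9, a chemokine receptor gene, was 3.51-fold lower (-1.81, SE 0.06) and Irf7 2.39-fold lower (-1.26, SE 0.06), while Siglech (-0.20) did not pass. The median (0.03) and mean (0.14) of the list were above 0 while camera, which compares with other genes, pointed down without passing (adjusted p = 0.327). The median turned below 0 under all 6 other scalings, to -0.29 with spike-in scaling.

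Class II presentation genes shifted slightly downward. Of 11 tested 6 fell, 2 rose and 3 did not pass (the same when adjusted over the list alone), with a median of -0.27 that lay between -0.14 and -0.59 over the 7 scalings. Cd74, the invariant chain gene, fell to a log2 difference of -0.49 (SE 0.07) and H2-Eb1 to -0.40 (SE 0.07), whereas the peptide-loading genes H2-DMa and H2-DMb1 each had 0.37, calls that were lost under quantile normalization, in the matrix values, with spike-in scaling and with the brightness trend removed. Without negative replicate 1 or 2, H2-DMa and H2-Eb1 did not pass (adjusted p of up to 0.064 and 0.0758), nor did Cd74 and H2-DMb1 without negative replicate 1 (0.0561 and 0.0759). The camera adjusted p of 0.0481 lay at the threshold, was 0.292 with an estimated correlation, and passed under only 6 of the 17 alternatives, whose values reached 0.124, the value without positive replicate 2. It was also lost without negative replicate 1 (0.0522) and negative replicate 2 (0.0816).

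The transcription factor list of myeloid and dendritic cells did not shift (camera adjusted p = 0.999). Of 27 tested 13 rose, 8 fell and 6 did not pass (14 and 8 when adjusted over the list alone). Nfil3 rose 3.22-fold (log2 difference 1.69, SE 0.07), Zeb2 2.32-fold (1.21, SE 0.06) and Spi1, which encodes PU.1, by 0.48, while Egr1 fell (-1.40, SE 0.07), as did Irf7 and Gfi1 (-0.68). The list's median of 0.21 turned to -0.11 with spike-in scaling. Of 25 cytokine and chemokine receptor genes 14 rose, 5 fell and 6 did not pass (14 and 6 when adjusted over the list alone), and the list did not pass camera (adjusted p = 0.327), with a median of 0.30 that turned to -0.02 with spike-in scaling. Its highest values were those of Cx3cr1, Ccr2 and Csf1r, the M-CSF receptor gene, at 6.68-fold (2.74, SE 0.06), whose 3 probes ranged from 0.66 to 2.91. The 14 receptor genes that rose include Flt3, for which no direction can be given.

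B lineage genes shifted upward (camera adjusted p = 0.0481, and 0.292 with an estimated correlation). Of 14 tested 10 rose, 2 fell and 2 did not pass (11 and 2 when adjusted over the list alone), with a median log2 difference of 0.73. With spike-in scaling 7 rose and 3 fell (median 0.41). After Il7r came the adaptor gene Blnk at 3.29-fold (1.72, SE 0.06) and the recombinase gene Rag2 at 2.6-fold (1.38, SE 0.07), and Vpreb3 was at least 2.57-fold higher because no negative array was above background. Rag1 (0.72) and Dntt (1.11), active in early lymphoid cells, rose, Cd22 (-0.56) and Foxo1 (-0.52) fell, and Ebf1 and Ms4a1 were not above background on any array. The call ended under 8 of the 17 alternatives, whose values reached 0.0858, among them leaving out positive replicate 1 (0.0543) or 2 (0.058).

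Genes of the T, NK and innate lymphoid lineage shifted downward (camera adjusted p = 0.0281, and 0.292 with an estimated correlation). Of 24 on the array only 14 passed the filter on dim probes. Tcf7, Bcl11b, Cd3d, Cd3g, Tbx21 and Eomes were among those not tested, so the shift does not cover them. Of the 14 tested 7 fell, 3 rose and 4 did not pass (8 and 4 when adjusted over the list alone). Gata3, a transcription factor of T cells and innate lymphoid cells, was 4.17-fold lower (log2 difference -2.06, SE 0.05) and Rora 4.4-fold lower (-2.14, SE 0.08). Notch3 was at least 1.23-fold lower, with no positive array above background, and the NK receptor gene Klrd1 was 2.55-fold higher (1.35, SE 0.16). The call ended under 9 of the 17 alternatives, whose values reached 0.123, among them leaving out positive replicate 2 (0.0529). Notch3 lost its call with normexp correction. Plasma cell genes rose in 5 and fell in 1 of 6 tested (the same when adjusted over the list alone), with no shift in camera (adjusted p = 0.147). With the brightness trend removed 3 rose, and with spike-in scaling 2, where the median was 0.06 against 0.37. Jchain, which joins polymeric antibodies, was 6.3-fold higher (2.65, SE 0.08), Edem1 (0.78) and Derl3 (0.42) rose less, and Prdm1 fell (-0.73, SE 0.15). Derl3 did not pass without either negative array (adjusted p of up to 0.0896) or with spike-in scaling, and Prdm1 not with normexp correction.

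Stem cell and multipotency genes fell together. Of 30 tested 24 fell, 1 rose and 5 did not pass (25 and 1 when adjusted over the list alone), and the list shifted downward in camera (adjusted p = 1.33e-11, and 0.292 with an estimated correlation). Its median log2 difference was -1.05, or -0.83 with the 4 genes not above background in the positive group set to their bound. Besides Esam, the protein C receptor gene Procr was 6.12-fold lower (-2.61, SE 0.12) and Hlf, a transcription factor of blood stem cells, 5.2-fold lower (-2.38, SE 0.07). Hoxa9 (-0.69) and Meis1 (-0.89) fell as well. The 1 gene counted as higher was Cd34 (0.26), for which no direction can be given. Under all 7 scalings the list's median stayed between -0.72 and -1.36.

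Megakaryocyte and erythroid genes fell as well. Of 27 tested 19 fell, 3 rose and 5 did not pass (the same when adjusted over the list alone), with a camera adjusted p of 7.17e-07 (0.292 with an estimated correlation) and a median of -0.91, or -0.50 with 3 genes set to their bound. With normexp correction the median was -0.31, with 15 lower and 4 higher, and over all 7 scalings it lay between -0.31 and -1.23. The platelet factor 4 gene Pf4 was 3.47-fold lower (-1.80, SE 0.07) and the carbonic anhydrase gene Car2 3.2-fold lower (-1.68, SE 0.05). Gp5 was at least 1.41-fold lower. Its call was lost without either negative array, with the replicate block (limma adjusted p = 0.0561), with no filter and with normexp correction. The erythroid regulator gene Klf1 (0.22, with no positive array above background) did not pass, and the transferrin receptor gene Tfrc, also used by dividing cells, rose (1.47). Mast cell, basophil and eosinophil genes did not shift (camera adjusted p = 0.811): of 12 tested 5 rose, 3 fell and 4 did not pass (the same when adjusted over the list alone). The eosinophil peroxidase gene Epx was 2.94-fold higher (1.56, SE 0.13) and Mcpt8 1.79-fold higher (0.84, SE 0.15), while Gata2 was 2.22-fold lower (-1.15, SE 0.06) and Il5ra 1.9-fold lower (-0.92, SE 0.11). Mcpt8 did not pass without either negative array (adjusted p of up to 0.0692). The list's median and mean (both 0.17) were above 0 and its camera direction was down, and the median turned to -0.14 with spike-in scaling.

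Genes of the cell cycle rose throughout. All 25 tested S phase genes and all 26 tested G2 and M phase genes rose, with the same counts when adjusted over each list alone. The median log2 difference was 0.71 for S phase (camera adjusted p = 7.17e-07) and 1.12 for G2 and M phase (camera adjusted p = 1.62e-08), each with an adjusted p of 0.292 with an estimated correlation. In S phase Rrm2, a ribonucleotide reductase subunit gene, was 2.49-fold higher (1.32, SE 0.06), Rrm1 2.09-fold and Clspn 1.99-fold. In G2 and M phase the mitotic kinase gene Aurkb was 3.22-fold higher (1.69, SE 0.12), Ube2c 2.73-fold, Plk1 2.7-fold and Kif11 2.68-fold. Many of these genes are bright, and among bright genes higher calls prevailed. With the brightness trend removed, 20 of 25 S phase genes still rose (median 0.46) and 26 of 26 G2 and M phase genes (median 0.81), and with spike-in scaling 21 (median 0.39) and 26 (median 0.80) rose.

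Interferon-stimulated genes fell. Of 37 tested 21 fell, 7 rose and 9 did not pass (24 and 7 when adjusted over the list alone), with a median of -0.35 and a camera adjusted p of 2.62e-06 (0.292 with an estimated correlation). Over the 7 scalings the median lay between -0.35 and -0.67, and with spike-in scaling 29 fell and 4 rose. Oas2, an RNA sensor of the antiviral response, was 7.42-fold lower (log2 difference -2.89, SE 0.07, limma adjusted p = 0.000852), Ifit1 5.98-fold lower (-2.58, SE 0.17, adjusted p = 0.0019), Ifit3 5.64-fold lower (-2.50, SE 0.17, adjusted p = 0.00198, with 1 of 2 positive arrays above background) and Ddx58, which encodes RIG-I, 3.41-fold lower (-1.77, SE 0.06, adjusted p = 0.00115). The 7 that rose were Gbp3 (1.02), Ifi27l2a (0.86), Ly6e (0.60), Bst2 (0.46), Tap1 (0.29) and the immunoproteasome genes Psmb8 (0.76) and Psmb9 (0.44).

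Toll-like receptor genes did not shift as a list (camera adjusted p = 0.493). Of 18 tested 6 rose, 3 fell and 9 did not pass (the same when adjusted over the list alone). After Ly86, the largest increase measured above background on all 4 arrays was that of the receptor chaperone gene Unc93b1 at 2.08-fold (1.06, SE 0.06). Tlr4 was 1.99-fold lower (-0.99, SE 0.07). Tlr1 had a fitted increase of 2.84-fold (SE 0.42), but only 1 of 2 negative arrays was above background. The size of the Tlr1 increase and its rank against Unc93b1 are therefore not known. The Tlr1 call was lost without either positive array and, among others, with quantile normalization. The list's median of 0.16 turned to -0.16 with spike-in scaling. Lysosome and proteolysis genes shifted upward (camera adjusted p = 0.028, and 0.346 with an estimated correlation). Of 21 tested 14 rose, 3 fell and 4 did not pass (15 and 3 when adjusted over the list alone), led by the proteases Lgmn at 3-fold (1.58, SE 0.09) and Ctsz at 2.35-fold (1.23, SE 0.06), the thiol reductase gene Ifi30 at 2.86-fold (1.52, SE 0.08) and Hexa at 2.27-fold (1.18, SE 0.06). The call ended under 7 of the 17 alternatives, whose values reached 0.14, among them quantile normalization and the brightness trend removed (0.125), and with spike-in scaling 8 rose (median 0.07).

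Immediate early and heat shock genes, which respond to handling of cells, moved both ways. Of 17 tested 8 fell, 4 rose and 5 did not pass (the same when adjusted over the list alone), with a camera adjusted p of 0.0481 (0.292 with an estimated correlation) that passed under 7 of the 17 alternatives and was lost without negative replicate 2 (0.0814) or positive replicate 2 (0.0691). Egr1, Jun (-1.36, SE 0.07), Ier3 (-1.25, SE 0.12) and Fos (at least 1.78-fold lower, a call lost with normexp correction at an adjusted p of 0.938) fell, and the heat shock genes Hsp90aa1 (0.75) and Hspa1a (0.58) rose. Of 9 tested genes of bone marrow stroma and endothelium, cells that the gate should not hold, 5 fell, none rose and 4 did not pass (the same when adjusted over the list alone), with a camera adjusted p of 0.028 (0.292 with an estimated correlation) that passed under 11 of the 17 alternatives and was lost without positive replicate 2 (0.0579). With normexp correction 2 of the 9 rose and 2 fell (median -0.15). The endomucin gene Emcn, also carried by blood stem cells, was 2.33-fold lower (-1.22, SE 0.06), Vcam1 at least 2.53-fold lower, Col1a2 1.45-fold lower (-0.54, SE 0.11) and Cxcl12 1.41-fold lower (-0.49, SE 0.13). Col1a2 and Cxcl12 did not pass without either negative array or with normexp correction, nor did Cxcl12 without positive replicate 1. Cxcl12 also lost its call with the replicate block (limma adjusted p = 0.0765) and quantile normalization (0.0734). The same held for the deposited matrix values (0.0724) and no filter (0.0691). Of the sex-linked genes Ddx3y (-0.14) and Eif2s3y (0.03) did not pass, the Y-linked Uty fell (-0.50, SE 0.09, limma adjusted p = 0.0144, and 0.057 without negative replicate 2; the call was also lost with normexp correction), and Xist and Kdm5d were not tested.

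**Figure D3:**
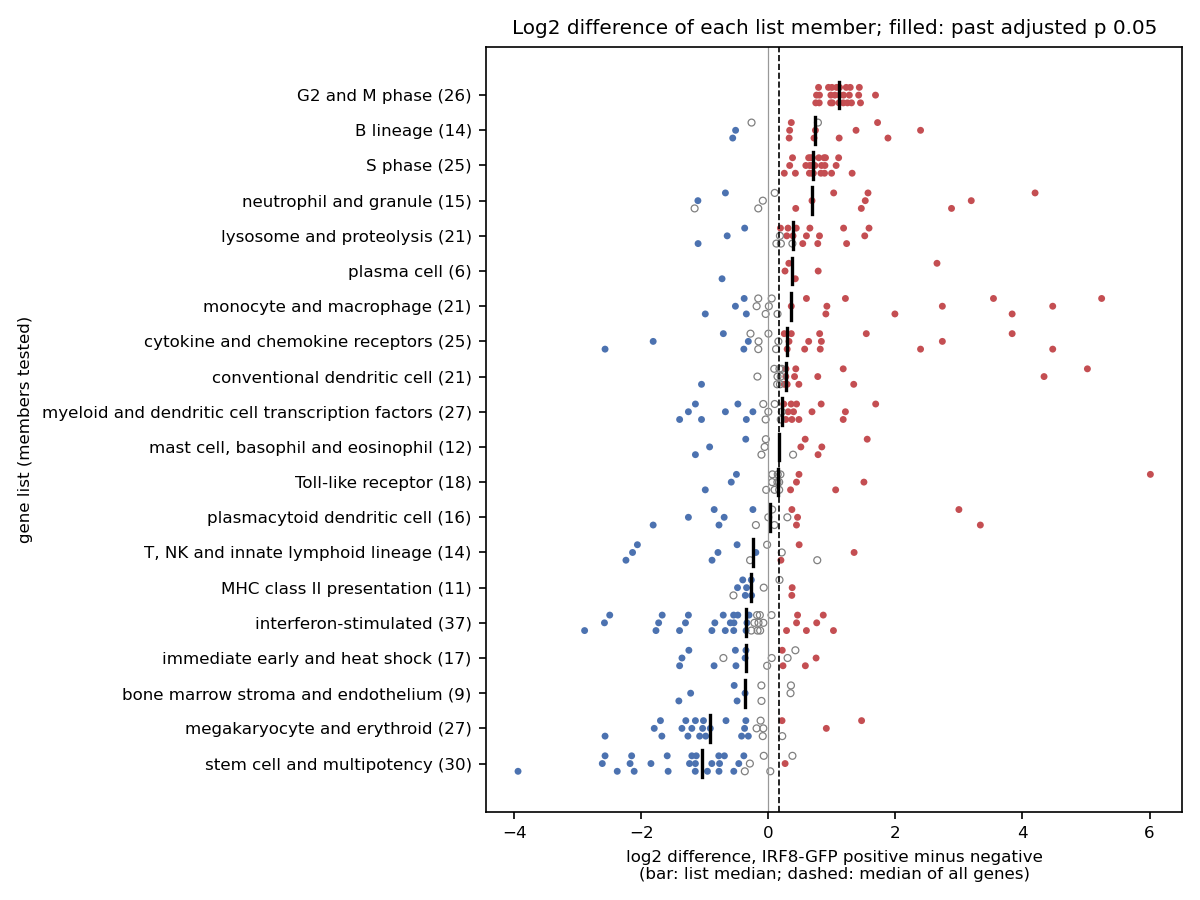
Log2 difference (IRF8-GFP positive minus negative) of each tested member of the 20 lists, ordered by list median (black bar), with members past an adjusted p of 0.05 filled, genes with only a bound drawn at their fitted value and the dashed line at the median of all genes, 0.16. All 26 tested G2 and M phase genes and all 25 S phase genes lie above 0, 24 of 30 stem cell genes fell, and monocyte, granule and receptor lists hold a few members far above the rest.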

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

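Spike-in scaling, the removal of the brightness trend by cyclic loess and the centring on the tested genes' median were chosen after seeing the data. The Irf8 difference kept its direction and its call under all 17 alternatives run for it, between 3.22 and 3.60. Within-group correlations stayed above those between groups in all 5 alternatives run for them. For the 92 other named genes, 1476 of 1543 values kept direction and call, 59 lost the call, 29 of these on leaving out an array, and 8 turned direction, those of Cd34 and Flt3. Signal over background limits the dim end, where normexp correction shrinks differences and folds are often only bounds. No fit with slide or scan as a block was run, since all arrays share 1 slide and scan day. With an array left out, the lone array was assumed to vary like the other group. The replicate number as a block gave 13946 calls. Deviations of same-numbered arrays correlated by only 0.0971 across genes, a measure that a shift of all genes alike does not change. The log2 spike-in mean was higher on exp 2 than on exp 1 in both groups. It was 11.99 against 11.64 for the negative and 11.93 against 11.49 for the positive arrays. The 75th percentile of the signal was higher on exp 2 as well. A pairing of the arrays by number is therefore not excluded. Calls could also end because fewer genes were tested (stricter filter) or fewer arrays used, or because the threshold was stricter; otherwise the cause was not tested.

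At an adjusted p of 0.01 there were 7861 calls, 5002 higher and 2859 lower. Leaving out arrays gave 7612 to 12774 calls, 4760 to 8002 higher, 2852 to 4772 lower and 7 to 11 lists, with adjusted p-values of 0.0332 to 0.124 for MHC class II presentation, 0.0346 to 0.058 for B lineage, 0.0332 to 0.0529 for T, NK and innate lymphoid, 0.0343 to 0.0814 for immediate early and 0.0285 to 0.0579 for stroma genes. With spike-in scaling 3171 were higher and 8211 lower (217 and 2352 at 2-fold), Cd34 was -0.054 and Flt3 -0.067, and adjusted p-values were 0.0747 for conventional dendritic cell, T, NK and innate lymphoid, immediate early and stroma genes, 0.0908 for MHC class II presentation, 0.026 for monocyte and 0.00579 for neutrophil genes. With the brightness trend removed 5542 were higher, Cd34 was -0.21 and Flt3 -0.17, and values were 0.12 for conventional dendritic cell, 0.0399 for neutrophil, 0.0501 for T, NK and innate lymphoid and for stroma, 0.125 for lysosome and 0.0736 for immediate early genes. Quantile normalization gave -0.14 for Cd34, -0.22 for Flt3, 0.14 for conventional dendritic cell and lysosome, 0.04996 for neutrophil, 0.0564 for T, NK and innate lymphoid and 0.0733 for immediate early genes. The deposited matrix values gave -0.14 for Cd34, -0.23 for Flt3, 0.14 for conventional dendritic cell and lysosome, 0.0488 for neutrophil, 0.0569 for T, NK and innate lymphoid and 0.071 for immediate early genes. Normexp correction gave 651 calls at 2-fold (272 higher, 379 lower), 0.0847 for conventional dendritic cell and lysosome, 0.0629 for MHC class II presentation and 0.0776 for stroma genes. Without a filter 14564 were higher (1218 at 2-fold), with 0.0629 for conventional dendritic cell and B lineage, 0.123 for T, NK and innate lymphoid and 0.128 for lysosome genes.

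Only probes above background on all 4 arrays gave 758 lower calls at 2-fold and 5 lists, with 0.114 for conventional dendritic cell, 0.0586 for MHC class II presentation, 0.0858 for B lineage and immediate early, 0.0565 for T, NK and innate lymphoid, and 0.0591 for lysosome and stroma genes. The replicate block gave 6 lists, with 0.0515 for MHC class II presentation, T, NK and innate lymphoid and lysosome, 0.0627 for B lineage, 0.0607 for immediate early and 0.0542 for stroma genes. Centring on detected probes gave 0.0537 for MHC class II presentation and immediate early genes. An intensity trend, with or without robust estimation, gave 0.0546 for MHC class II presentation and 0.0687 for B lineage. The mean of a gene's probes gave 0.0669 for MHC class II presentation, 0.0354 for monocyte, 0.0648 for B lineage, 0.0543 for T, NK and innate lymphoid and 0.0685 for immediate early genes. With an estimated correlation 0 lists passed, at 0.292 for conventional dendritic cell, MHC class II presentation, B, T, NK and innate lymphoid, megakaryocyte and erythroid, stem cell, interferon-stimulated, S phase, G2 and M phase, immediate early and stroma genes, and 0.346 for lysosome genes. The directional fry test gave 0.000804 for monocyte, 0.00129 for neutrophil and plasma cell, 0.00141 for Toll-like receptor, 0.0456 for transcription factor and 0.0024 for receptor genes. The mixed fry test gave 4.78e-05 for plasmacytoid dendritic cell, mast cell and transcription factor, 0.000153 for monocyte, 6.81e-05 for neutrophil and receptor, 3.9e-05 for Toll-like receptor and 0.000433 for plasma cell genes.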

Other observations

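The tests in this part were chosen after the results had been seen, except the camera tests of the fixed lists and their alternatives, which were planned apart from the 3 scalings added later.

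Gene families were scanned by their symbols. Of 210 families of at least 8 tested genes that share the letters of their symbol, 43 shifted in camera after adjustment over the families, 36 up and 7 down, and none did with an estimated correlation (smallest adjusted p 0.871, with 2 families below an unadjusted p of 0.05). Genes of the mitochondrial ribosome rose nearly throughout, with 46 of 48 tested Mrpl genes (median log2 difference 0.63, adjusted p = 7.85e-08) and 29 of 29 Mrps genes (0.64, adjusted p = 5.39e-06), each at 0.871 with an estimated correlation, as did 19 of 19 nucleoporin genes (Nup, median 0.76), 14 of 14 proteasome genes (Psmd, 0.67) and 46 of 53 translation initiation genes (Eif, 0.51). Their medians stayed above 0 under all 7 scalings, at 0.34 for Mrpl, 0.46 for Nup and 0.17 for Eif with the brightness trend removed. The counts were made in the reported scaling alone. There 8611 of all 22362 genes were higher, and 3750 of 5591 in the brightest of 4 equal groups. Cytosolic ribosomal protein genes (Rpl) had a median of 0.38 that turned to -0.01 with quantile normalization and -0.11 with the brightness trend removed, so no direction can be given for them.

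Among the families that fell were the immunity-associated GTPases (Gimap), with 6 of 8 lower and 1 higher (median -0.82, adjusted p = 0.0133, and 0.871 with an estimated correlation), led by Gimap8 (-2.43, SE 0.05) and Gimap3 (-1.73, SE 0.17), while Gimap4 rose (0.28). The Hoxa genes had 6 of 9 lower and none higher (median -0.78, adjusted p = 0.00553, and 0.871 with an estimated correlation), led by Hoxa10 (-1.59, SE 0.08), but 4 of these 9, Hoxa10 among them, also belong to the fixed stem cell list, so this partly repeats that list's result. Of 9 clustered protocadherin genes (Pcdhb) 7 were lower and none higher (median -1.71, or -0.54 with 4 genes set to their bound, adjusted p = 0.00412, and 0.871 with an estimated correlation). These 4 were not well above background in the positive group, normexp correction shrank the median to -0.26, and probes of such similar genes can share signal. All 3 medians were below 0 under all 7 scalings.

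The positive arrays had fewer spots well above background and a 75th percentile lower by 0.43 on the log2 scale (difference -0.43). A dimming of all signals alike does not account for this. The mean of 7 bright spike-in controls differed by only -0.11. After spike-in scaling the percentile of both positive arrays was still below that of both negative arrays, by -0.32 on average. The range within a group was at most 0.06. These controls were compared only by their mean log2 signal, 11.49 to 11.99 per array, against 8.31 to 9.08 for the percentile. They therefore cannot exclude an array effect that acts more on dimmer signals. The remaining drop of 0.318 could come from such an effect, from less labelled RNA, from RNA of lower integrity or from a real difference in how many transcripts these cells hold. These cannot be told apart, also because no RNA amount or integrity is given. The direction of the majority of weak calls depends on this drop, since spike-in scaling gives 3171 higher and 8211 lower calls.

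Several granule, monocyte and conventional dendritic cell genes rose in the positive group, within a gate meant to remove lineage-positive cells, although the granule and monocyte lists did not shift in camera (adjusted p = 0.147) and the dendritic cell call was lost under 7 of 17 alternatives. Admixed mature neutrophils are argued against for the granule genes, because the 4 of 7 abundant mature neutrophil transcripts that could be tested had a median log2 difference of -0.60 (S100a9 -1.11, Camp -0.09 and S100a8 -1.16, the last 2 without passing, and Lcn2, which rose by 0.43), against 1.57 for Ctsg, Ms4a3, Elane, Mpo and Prtn3. Admixed mature dendritic cells or macrophages stay open: H2-Aa, H2-Ab1, H2-Eb1 and Cd74 had a median of -0.34, and the dimmest, H2-Aa, fell as well (-0.27), but all 4 were well above background on both negative arrays, where a small share would be hidden, and the 4 monocyte and macrophage markers tested moved apart (Lyz1 0.05 and Lyz2 0.01 without passing, Itgam -0.52, and the dimmest, Adgre1, 0.91). Cells from neighbouring gates in the positive sort, with less Sca-1 or some IL-7R, stay open too, since the drop of Ly6a (-0.96) and the rise of Il7r are what both spill-over and a gradient within the gate predict, and the 2 cannot be told apart on bulk arrays. Progenitors primed toward these lineages along with Irf8 remain a hypothesis that the design does not test.

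Interferon-stimulated genes were lower where Irf8, itself named as an interferon regulatory factor, was higher. Array scaling is argued against as the cause, because under the 3 scalings that do not shift all genes alike (quantile, normexp and loess) the list's median minus that of all genes was at most -0.60, with camera adjusted p-values from 3.99e-10 to 9.44e-07 (0.292 with an estimated correlation in the reported scaling). Dim probes near background are argued against too, because 36 of the 37 tested members were well above background on all 4 arrays. Their median of -0.34, with 20 lower and 7 higher, therefore nearly restates the list's result. The 28 of them brighter than the median gene had a median of -0.29, with 14 lower and 7 higher. A lower share of cells with an interferon response, or less of a stem-like state that carries it, may underlie the drop, and neither was tested.

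A further hypothesis was that genes beside Irf8 on its chromosome rise with it. The 10 nearest tested genes, 5 on each side, had a mean log2 difference of 0.35, at percentile 87.7 of 10000 random windows of 10 neighbouring genes, so a shared rise beyond that of other neighbouring genes was not seen. Of the 10, 6 were higher and 4 lower, among them Cox4i1 (0.65), Emc8 (0.86) and Mthfsd (-0.29).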
